A study of Mus musculus and Homo sapiens with 51 samples.

How the data were processed

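The deposited data are 2 tables of read counts per gene, 1 for the mouse tissues and 1 for SH-SY5Y cells. Per the labels' protocols, RNA was extracted with a Vazyme kit, mRNA was enriched, and libraries were sequenced by Novogene on an Illumina NovaSeq with paired-end reads. Per the submitters' processing notes, reads were trimmed with fastp 0.23.2 and aligned with HISAT2 2.2.1. Those notes name 4 genome builds for the series without saying which table used which; the counting tool and annotation are not given in the sources used here, so no coordinates are printed. The counts in both tables are as deposited by the authors, with no normalization seen in the values: they are whole numbers whose totals differ between libraries. The mouse table gives gene identifiers and symbols in human-style capitals and holds 14744 lines for 14721 symbols, with no genes of the mitochondrial genome, the mouse MHC or haemoglobin. Its symbols were used as given. The cell table holds 17112 symbols. Lines that share a symbol were summed (14 symbols in mouse, 31 in cells), and 1 line repeated exactly in each table was used once.

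Columns were assigned to samples only where the label's name matched. Of 51 samples, 50 had a column. The missing 1 is a vehicle brain library, so that group has 2 libraries where the design assumed 3, and 2 columns of the mouse table match no label and were not used. The labels do not say that replicates are separate cultures or animals, so p-values measure the spread between libraries. Groups and totals per library were: brain C57 17527035 to 18236596, vehicle 16396406 to 19214210 and treated 8262628 to 17533066; colon C57 2561466 to 15124684, vehicle 4089809 to 15008212 and treated 3927473 to 14205870; cells with supernatant 43924811 to 49436496, with butyrate 30847911 to 36325021, with oleoylethanolamide 37072781 to 41965647, untreated in batch 1 31757859 to 36606927 and in batch 2 40740826 to 41730608. PCR duplicates cannot be told from separate molecules in counts.

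Tests were run with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The groups of a tissue shared one fit, as did the groups of a labelled cell batch; the difference of tissue effects used all mouse libraries and the differences of cell treatment effects all cell libraries. Log2 fold changes are edgeR's, standard errors are the fold divided by the root of its F statistic, and CPM were computed on TMM-scaled totals. Values per library of marker genes, including those of OMP, HOXB13, MYH11, PRPF8 and CDC42, are CPM on plain totals. Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison; lists with at least 5 tested genes were used, 35 in brain, 42 in colon and 34 in cells.

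The genes named were chosen by a rule set before the data were examined: the 10 largest increases and decreases among called genes with a mean of at least 5 CPM, a known symbol and no overlap between groups; up to 4 members with the smallest p from lists that passed camera or had at least 2 called members; and preset strain, oleoylethanolamide, PPARA and butyrate genes. Where fewer than 5 genes were called, these and the 5 with the smallest p were named. From the genes this rule gives, a part is described. Of the genes given by the rule, 1 is not reported here. Marker genes of the library sets and of gut layers (such as PRPF8, HOXB13 and MYH11) were chosen after their values were seen.

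The comparisons against untreated cells of the same gene set, the covariates for striatal genes, gut layers and transcript length, the division of the brain vehicle controls and the omission of gut-region libraries were added after seeing the data. Transcript length was the longest annotated transcript of the gene in GENCODE M21, found for 99.9% of tested genes; it served for lengths only, since the build of the mouse table is not settled. Alternatives set before the data were examined were DESeq2 1.42.0, RLE factors, no filter, a mean CPM of at least 1, a fold of 2, limma voom with sample weights, each replicate left out, only the groups compared, 1 surrogate variable (sva 3.50.0), a replicate block and, for cells, all libraries together or all 6 untreated libraries together.

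Each test was first run on simulated counts drawn from the real genes' means and spreads with 200 genes changed. With a simulated fold of 2, edgeR recovered 62.7% of changed genes in the brain strain and the brain treatment comparison, 22.4% in colon strain, 34.3% in colon treatment and 82.1% for butyrate against untreated cells of the same gene set. With a fold of 4 these were 83.3%, 92.4%, 60.6%, 80.3% and 95.5%. Of the calls in these simulations, 7.9%, 7.3%, 6.6%, 4.8% and 5% were false. The share was 10.1% for supernatant and 5% for oleoylethanolamide against the same gene set and 9.3% for oleoylethanolamide minus butyrate. Shared controls were simulated 20 times with unchanged groups. Pairs of libraries within a group were checked for duplication, and all differed by more than counting noise. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.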

Results

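RNA was sequenced from the brain cortex and colon of mice and from SH-SY5Y cells, a human neuroblastoma line. The mice were C57 controls and BTBR mice, an inbred strain used as a model of autism, given either vehicle or live L. asaccharolyticus by mouth. Brain cortex gave 3 C57, 2 vehicle BTBR and 6 bacterium-treated BTBR libraries, and colon gave 5, 9 and 10. Cells were sampled after 24 h without treatment (6 libraries, 3 in each of 2 labelled batches) or with bacterial supernatant, butyrate or oleoylethanolamide (3 libraries each). Oleoylethanolamide is a lipid amide that activates the nuclear receptor PPARA, and butyrate is a short-chain fatty acid made by gut bacteria. Total counts per library ran from 8262628 to 19214210 in brain, from 2561466 to 15124684 in colon and from 30847911 to 49436496 in cells.

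The first comparison asks how the cortex of vehicle BTBR mice differs from that of C57 mice. Among genes switched on by neuronal firing 5 of 16, and among heat shock genes 7 of 14, were called lower in BTBR cortex. Neither list passed with an estimated correlation between genes (adjusted p = 0.28 and 0.16). The edgeR test called 754 of 13248 genes, 383 higher and 371 lower in BTBR. The lipid enzyme gene PLA2G4E and GABRA2, which encodes a receptor subunit for the transmitter GABA, were among those that were higher. The count rested on few libraries: it was 85 without vehicle replicate 2, which leaves 1 vehicle library, 125 without C57 replicate 2, 272 without C57 replicate 1 and 466 without C57 replicate 3.

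ARC, which marks recently active synapses, averaged 111 ± 14.1 CPM (SD, n = 2) in vehicle BTBR and 701 ± 49.9 CPM (SD, n = 3) in C57 cortex (log2 fold change -2.66, adjusted p = 0.0142). The activity-induced transcription factor genes EGR2 (-2.86), EGR3 (-1.64) and FOSL2 (-1.31) were lower with it. Of 16 immediate early genes, 5 were called, all lower, and 12 were lower when adjusted over the list alone. The list as a whole was lower by camera (adjusted p = 1.1e-10), but not with an estimated correlation between genes (adjusted p = 0.28). BDNF, the gene of a neurotrophin that activity induces, fell by 1.56 on the log2 scale, HOMER1, a scaffold gene of the excitatory synapse, by 1.58, and PTGS2, a cyclooxygenase gene, by 2.01. Among 14 heat shock genes, 7 were lower, or 9 adjusted over the list alone, with HSPA1B at -1.85, HSPA8 at -0.94 and DNAJB1 at -0.87. That list passed camera as well (adjusted p = 8.1e-09), though not with an estimated correlation (adjusted p = 0.16). In sterol metabolism, INSIG1 fell by 0.76 and IDI1 by 0.85, and the list had 3 lower genes of 23 (5 adjusted over the list alone; adjusted p = 0.67 with an estimated correlation). The PPARA target gene ANGPTL4 (1.34) was higher, among 3 called in a list of 22 (4 adjusted over the list alone; adjusted p = 0.75 with an estimated correlation). The glycolysis gene ENO1 was lower (-0.91) and the glucose transporter gene SLC2A1 higher (0.74).

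Further genes separated the strains without overlap between libraries. With 2 against 3 libraries this held for 6019 of the 13248 genes tested, so by itself it says little. MROH7 (2.72), PLA2G4E (2.51), a phospholipase gene whose product makes precursors of oleoylethanolamide and related amides, the interferon-induced gene XAF1 (2.17) and HDDC3 (2.16) were higher in BTBR, and the myosin gene MYO7A was lower (-3.19). Among 8 genes chosen in advance as known to differ between the strains, WDFY1 (1.49), GABRA2 (1.18), which encodes a GABA receptor subunit, and ITPR3 (0.97) were higher and IDE (-1.14) was lower. RPL29 had the largest decrease named (-5.94), with PTTG1 (-5.42), TDG (-3.23) and HMGN2 (-2.95). Genes such as RPL29, TDG and HMGN2 share sequence with processed copies elsewhere in the genome, and counting can split reads between copies, so their values are uncertain. Of the clock genes, DBP was higher (1.07) and HLF lower (-1.02). The striatal genes DRD2 and ADORA2A averaged 38.1 and 68.1 CPM in BTBR against 5.44 and 9.84 CPM in C57 cortex, and neither was called (adjusted p = 0.13 and 0.15). The striatum list was higher in 10 of 10 members (median 2.05, camera adjusted p = 0.0023), the myelin list lower in 12 of 12 (median -0.59, camera adjusted p = 0.0015) and the hippocampus list higher (median 0.89, camera adjusted p = 0.030), each with an adjusted p = 0.72 with an estimated correlation. With the striatum list as a covariate, a setting added after seeing the data, 157 genes were called between the strains. Of 32 genes named for this comparison, 9 lost their call under it.

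**Figure D1:**
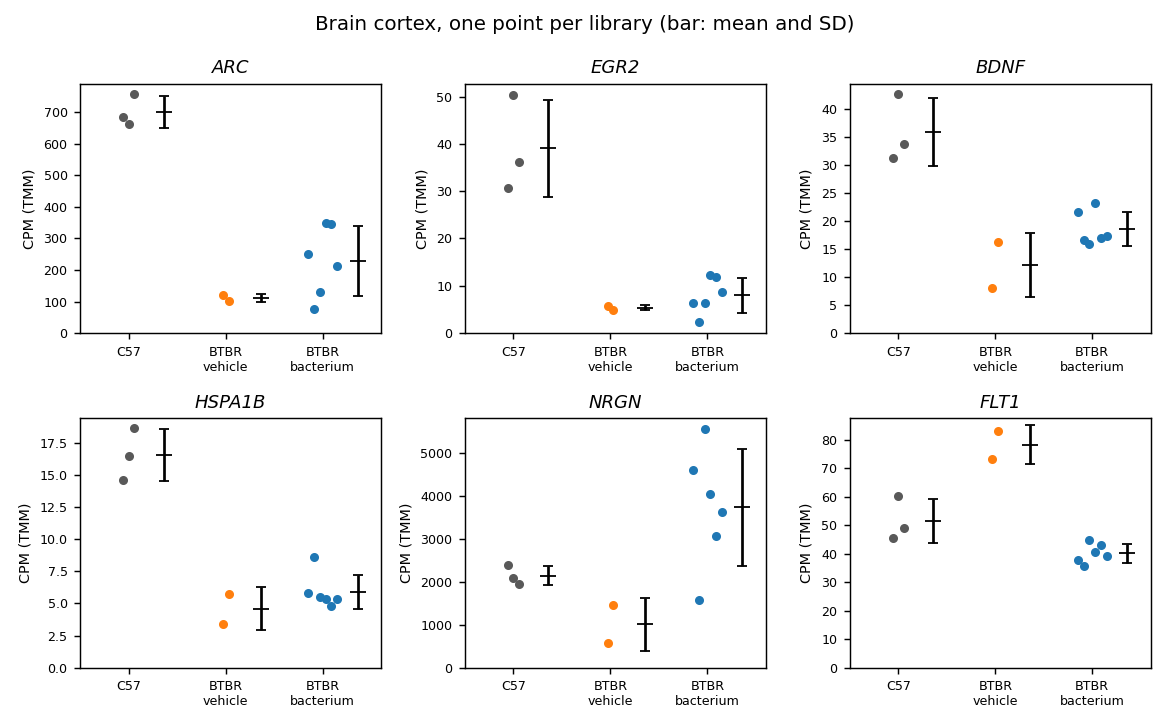
Normalized expression (CPM, y axis) of 6 genes in each brain cortex library, for C57, vehicle BTBR and bacterium-treated BTBR mice; points are libraries, and the bar gives the mean and SD. ARC averaged 701 CPM in the 3 C57 libraries and 111 CPM in the 2 vehicle BTBR libraries.

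The second comparison asks what oral treatment with the bacterium did in BTBR cortex. By camera with its preset correlation, lists of nuclear respiration genes and synaptic vesicle genes were higher after treatment and the endothelial list was lower. None of these 3 lists passed with an estimated correlation (adjusted p = 0.79, 0.79 and 0.78). The test called 1811 genes, 749 higher and 1062 lower. Higher genes had short transcripts and lower genes long ones: median lengths were 2080 and 5049 bases, against 3500 over the genes tested. Region markers varied among treated libraries, with DRD2 between 0.98 and 83.3 CPM and TTR, a choroid plexus gene, between 5.24 and 707 CPM. With vehicle they lay between 27.1 and 55.0 CPM and between 19.3 and 39.8 CPM. There were 6 genes called without vehicle replicate 2 and 1131 without vehicle replicate 3, where a single vehicle library is left and the spread comes from the other groups, 844 without treated replicate 1 and 2760 without treated replicate 2, and 0 were called by edgeR once each library's trend with transcript length was a covariate (2213 at unadjusted p below 0.05; the other tools were not run with it).

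NRGN, a calmodulin-binding gene of cortical dendrites, averaged 3733 CPM after treatment and 1012 CPM with vehicle (log2 fold change 1.88, adjusted p = 0.0194). RSPO1, a Wnt agonist gene (1.98), and FXYD7, a sodium pump regulator gene (1.501), were also higher. In the synaptic vesicle list, SNAP25 rose by 1.02, STX1A by 0.78, RAB3A by 0.55 and SYP by 0.52; 4 of 18 members were called and 5 adjusted over the list alone (adjusted p = 0.79 with an estimated correlation). Of 39 nuclear genes of oxidative phosphorylation 12 were higher, or 23 adjusted over the list alone, among them CYCS (0.71), NDUFB3 (0.79) and NDUFA8 (0.61) (adjusted p = 0.79 with an estimated correlation). The ribosomal protein genes RPL27 (0.70) and RPS23 (0.88) were called with them, 2 of 34 in their list and 0 adjusted over the list alone (adjusted p = 0.79 with an estimated correlation). Genes of inhibitory neurons went both ways: PVALB (1.66), SST (0.86) and NPY (0.71) were higher and DLX1 (-1.54) lower. The chaperone genes DNAJA1 (0.50) and CRYAB (0.82) were higher, as was ATF4 (0.60), a stress-response transcription factor gene.

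Among lower genes, the vascular receptor genes FLT1 (-0.96) and KDR (-1.44) and the adhesion gene PECAM1 (-1.14) belonged to an endothelial list with 6 of 10 members called (7 adjusted over the list alone; adjusted p = 0.78 with an estimated correlation). SLC2A1, the glucose transporter gene of the blood-brain barrier, fell by 0.86. Chromatin genes with links to autism, KMT2C (-0.83), KMT2A (-0.65) and POGZ (-0.68), were among 8 lower members of a list of 35 in which FOXP1 alone was called higher (1.03). That list did not pass camera (adjusted p = 0.14; adjusted p = 0.79 with an estimated correlation), and its median went from -0.16 to 0.068 with the length covariate. The clock genes PER3 and PER2 fell by 1.07 and 0.69. ACADVL, a gene of fatty acid oxidation, fell by 0.87, among 5 lower genes of 22 PPARA targets (5 adjusted over the list alone; adjusted p = 0.79 with an estimated correlation). RREB1 (-2.30), MAP3K1 (-2.22), RNPC3 (-1.95), NKTR (-1.85) and NOTCH1 (-1.79) had the largest decreases among the genes named. Genes that make or break down oleoylethanolamide were not called, with ABHD4 at -0.36 (adjusted p = 0.091) and NAAA at -0.36 (adjusted p = 0.14), and neither was the monocarboxylate transporter partner BSG (0.35, adjusted p = 0.10).

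With the length covariate, folds of the respiratory and ribosomal genes shrank: CYCS went from 0.71 ± 0.15 (SE) to 0.29 ± 0.19, NDUFB3 from 0.79 to 0.23 and RPS23 from 0.88 to -0.11. The respiration list went from a median of 0.40 to -0.031 (camera adjusted p = 0.82) and the ribosomal list from 0.44 to -0.28, now lower by camera (adjusted p = 0.0036). The synaptic vesicle list went from 0.32 to 0.53 (camera adjusted p = 3.0e-05) and the endothelial list from -0.73 to -0.53 (camera adjusted p = 0.019). Lists were tested with the covariate at the preset correlation only, and the covariate follows the groups (correlation -0.89). Further lists changed sign under it: the myelin median went from 0.036 to -0.65 (camera adjusted p = 0.013) and the choroid plexus median from 0.43 to -1.435 (camera adjusted p = 0.059). Other named genes shrank as well, with KDR going from -1.44 to -0.34, PECAM1 from -1.14 to -0.48, KMT2C from -0.83 to -0.19, PVALB from 1.66 to 0.75, CRYAB from 0.82 to 0.12, ATF4 from 0.60 to 0.12 and FXYD7 from 1.501 to 0.62. Those of FLT1 (-0.96 ± 0.12 to -0.93 ± 0.22), SLC2A1 (-0.86 to -0.83), PER3 (-1.07 to -1.04), ACADVL (-0.87 to -0.82) and SNAP25 (1.02 to 0.97) moved little, and their calls ended as the standard errors grew (adjusted p = 0.098, 0.10, 0.069, 0.13 and 0.31).

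**Figure D2:**
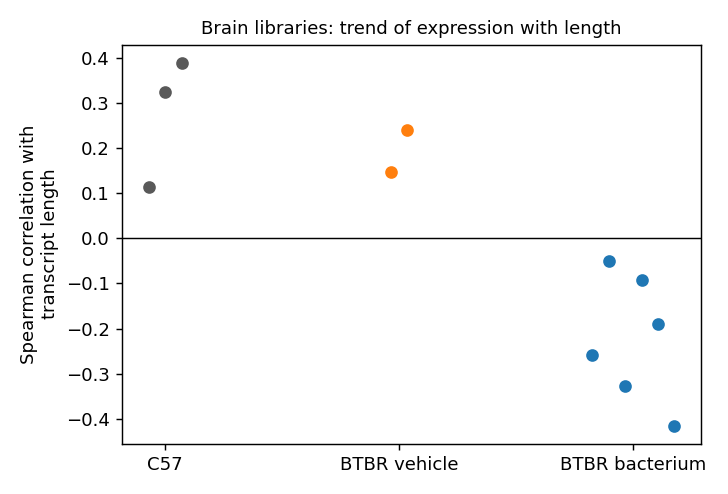
Spearman correlation across genes (y axis) between each brain library's expression, relative to the mean library, and transcript length, with one point per library in 3 groups. The 6 treated libraries lie between -0.42 and -0.051, and the other libraries between 0.11 and 0.39.

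A further question is whether treatment moved strain-altered genes back towards C57 levels. In brain, 207 genes were called in both comparisons and 200 of them went in opposite directions, 125 higher in BTBR and then lower with treatment, 75 the reverse. Independent lists would share 30.7 and 21. The treatment calls numbered 6 without vehicle replicate 2, with 1 vehicle library left, and 0 by edgeR with the length covariate, and no more than these could then be in the overlap. Both comparisons use the same vehicle libraries, and simulated unchanged treatment gave a median of 0 and at most 1 such gene. Those simulations called a median of 0 and at most 1 treatment gene, so their overlap could not be larger. They therefore cannot show how many of the 200 genes come from the shared controls. With the controls divided, a test added after seeing the data that leaves 1 vehicle library per comparison, 9 of 13 genes called in both were opposite with vehicle replicate 3 for strain, and 2 of 2 the other way round. Fewer genes were called then (86 and 1128, and 516 and 6, for strain and treatment), so part of the 200 may come from the shared controls and the size of that part stays open. Among all 754 strain calls, 85.8% had the opposite sign after treatment, against a simulated median of 77.0% with no treatment effect, and with divided controls it was 58.1% and 70.7%.

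The colon comparison of vehicle BTBR with C57 mice showed higher expression of clock output genes in BTBR, in the only list of 42 that passed with an estimated correlation (adjusted p = 0.031). Macrophage genes were higher, and heat shock, glycolysis and tight junction genes lower, in part of their members, and these lists did not pass with an estimated correlation (adjusted p = 0.38, 0.10, 0.057 and 0.51). Cell-type lists moved with them by camera: endothelial (10 of 10 members, median 1.04, adjusted p = 0.00035), B cell (14 of 14, 1.72, 0.0023) and fibroblast genes (15 of 15, 0.51, 0.030) were higher and absorptive cell genes lower (-1.22, 0.026), none with an estimated correlation (adjusted p = 0.51, 0.63, 0.71 and 0.52). The test called 1271 of 13354 genes, 428 higher and 843 lower. C57 replicate 1 carried small intestine transcripts, and the count was 586 without it and 822 without C57 replicate 2. Of the genes called in brain and colon alike, 81 of 105 had the same direction (25 higher and 56 lower, against 11.1 and 21.5 for independent lists).

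The circadian list had 8 higher and 2 lower genes of 15, or 9 and 3 adjusted over the list alone, and it passed camera with an estimated correlation (adjusted p = 0.031). DBP, an output gene of the clock, averaged 152 CPM in vehicle BTBR and 13.3 CPM in C57 colon (log2 fold change 3.49, adjusted p = 5.4e-07). CIART (3.49), PER3 (2.93) and TEF (2.202) were higher with it. Heat shock genes were lower, 7 of 14 called and 10 adjusted over the list alone, with HSPA1A at -4.18, HSPA1B at -3.60, HSPA8 at -1.33 and DNAJB1 at -1.31 (adjusted p = 0.10 with an estimated correlation). The glycolysis genes LDHA (-1.68) and ENO1 (-1.36) were among 9 lower members of 27, 13 adjusted over the list alone (adjusted p = 0.057 with an estimated correlation). Of 12 macrophage and dendritic cell genes 6 were higher, 9 adjusted over the list alone, including the growth factor receptor gene CSF1R (1.24), CD68 (1.57) and the complement gene C1QC (1.11) (adjusted p = 0.38 with an estimated correlation). JCHAIN, which joins antibody subunits, was higher (1.70), as were the detoxification genes NQO1 (1.46) and GSTA4 (1.52). The immediate early genes FOS (-1.65) and JUN (-0.90) were among 3 lower of 15, 6 adjusted over the list alone (adjusted p = 0.51 with an estimated correlation).

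**Figure D3:**
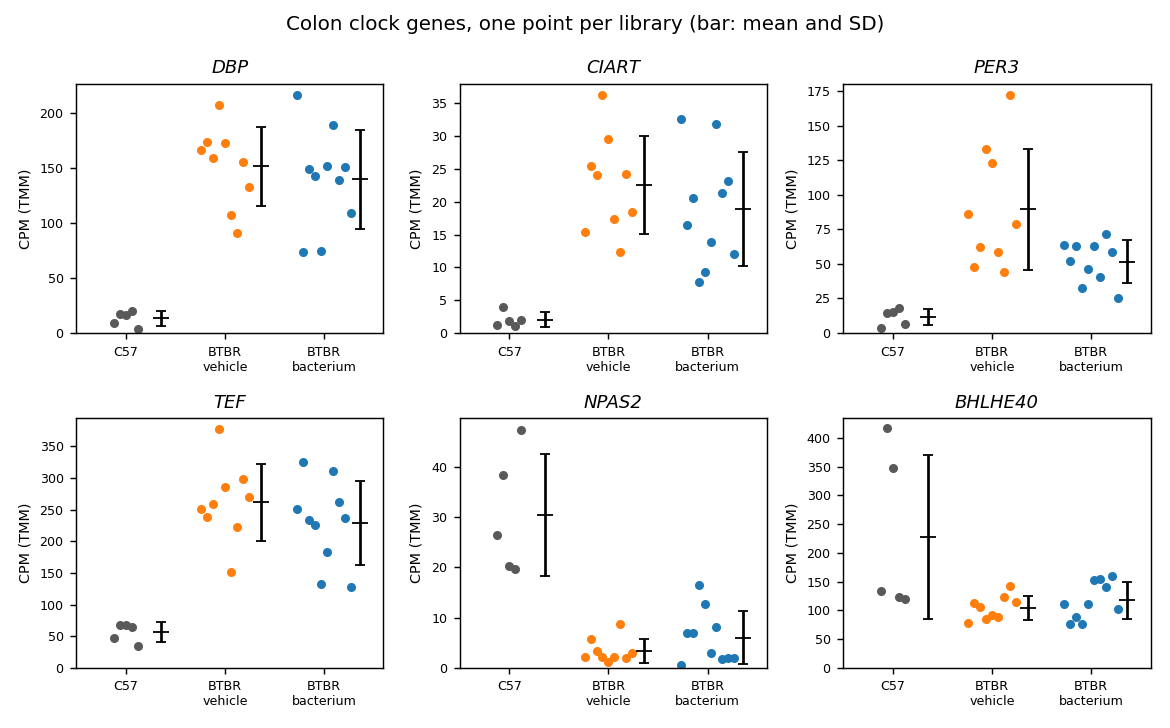
Normalized expression (CPM, y axis) of 6 clock genes in each colon library, for C57, vehicle BTBR and bacterium-treated BTBR mice; points are libraries, and the bar gives the mean and SD. DBP averaged 13.3 CPM in C57 colon and 152 CPM in vehicle BTBR colon, while NPAS2 and BHLHE40 were lower in BTBR.

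Part of the barrier genes were lower in BTBR colon, with C57 replicate 1 setting several of the folds. The tight junction genes OCLN (-1.56), CLDN4 (-3.21) and CLDN8 (-2.51) were among 4 lower members of 18, 6 adjusted over the list alone (adjusted p = 0.51 with an estimated correlation). DUOX2 (-2.12) and its partner DUOXA2 (-3.65), which make hydrogen peroxide at the gut surface, were lower, and so were the butyrate transport genes SLC16A1 (-1.56), SLC16A3 (-2.75) and ABCG2 (-1.97). The small intestine genes ANPEP (-7.84) and APOA1 (-14.94) and the antimicrobial gene REG3G (-9.65) were high in C57 replicate 1. Without that library CLDN4, OCLN, DUOX2, SLC16A3, ABCG2, ANPEP and REG3G lost their call, as did CD68, C1QC, JCHAIN and FOS, while CLDN8, DUOXA2 and SLC16A1 kept it. In C57 replicate 1 APOA1 reached 50614 CPM, against at most 63.5 CPM in the other C57 libraries. LPO, a secreted peroxidase gene, averaged 663 ± 260 CPM (SD, n = 9) in vehicle BTBR against 7.26 ± 5.62 CPM (SD, n = 5) in C57 (6.54). NR2E3 (5.18), HAL (5.18), AFM (4.18) and HDDC3 (3.85) were also higher. ST6GALNAC1, a mucin sialyltransferase gene, averaged 18.9 CPM in BTBR and reached at most 1 count in a C57 library. ST3GAL4, another sialyltransferase gene, was lower (-7.04). It reached 3206 CPM in C57 replicate 1, against 220 to 374 CPM in the other C57 libraries. SP110 averaged 0.17 CPM in BTBR and 14.5 CPM in C57. RPL29 (-7.69) and TDG (-4.68) were lower as in brain, with the same doubt about copies. WDFY1 was higher (1.98), and IDE (-0.67) was not called (adjusted p = 0.053).

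Treatment with the bacterium gave no called gene in colon. By camera with its preset correlation, lists of the enteric nervous system, smooth muscle and B cells were higher and those of goblet cells and absorptive cells lower, and of 18 lists past that test 0 passed with an estimated correlation and 0 by fry. By edgeR 0 of 13354 genes were called, with 1547 at an unadjusted p below 0.05, while DESeq2 called 0 and limma voom 3. The genes with the smallest p were STRC, S1PR1 (1.25), RTL1, PER2 (-1.11) and SEMG1, each with an adjusted p of 0.39. Among treated libraries, HOXB13, a gene of the distal gut, lay between 0.21 and 566 CPM and MYH11, a smooth muscle gene, between 507 and 14842 CPM. With vehicle these lay between 13.2 and 454.5 CPM and between 1289.5 and 7305.4 CPM. EPCAM, an epithelial gene, lay between 99.0 and 1559 CPM with treatment and between 546 and 1571 CPM with vehicle. Unadjusted passes numbered 576 with the epithelial minus muscle score as covariate, 553 without 5 treated libraries and 2585 without 3 libraries of other gut regions. These settings were added after seeing the data, and the lists were not tested under them.

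The enteric neuron list was higher by camera (adjusted p = 1.4e-08; adjusted p = 0.54 with an estimated correlation), with 0 of 18 genes called over all genes and 12 adjusted over the list alone. SNAP91 (1.89), STMN2 (1.49) and RET (1.31), a receptor gene needed for enteric neurons, led it, and the cannabinoid receptor gene CNR1 stood at 1.495 (adjusted p = 0.40). Goblet cell genes were lower by camera (adjusted p = 2.8e-06; adjusted p = 0.41 with an estimated correlation), with CLCA1 at -1.66, ZG16 at -1.40 and FCGBP at -1.13; 0 were called over all genes and 1 adjusted over the list alone. The absorptive cell genes SLC26A3 (-1.26) and AQP8 (-1.25) and the adhesion gene CDH1 (-0.78) were not called either. TAGLN, a smooth muscle gene (1.85), LUM, a matrix gene (1.19), the B cell genes PAX5 (2.57) and CD79B (1.49) and the interferon-induced gene IFIT1 (2.00) were not called, with adjusted p between 0.39 and 0.41. The butyrate transporter gene SLC16A1 (-0.065, adjusted p = 0.93) and the short-chain fatty acid receptor gene FFAR2 (0.11, adjusted p = 0.93) were close to their vehicle levels, and OR51E2, another such receptor gene, stood at -1.98 (adjusted p = 0.39). With 0 genes called by edgeR after treatment, reversal cannot be judged from calls. Of the 1271 strain calls 55.6% had the opposite sign after treatment, against a simulated median of 63% with no effect and 47.7% and 48.3% with divided controls.

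The treatment effects in brain and colon were also compared by a test of their difference. In simulated counts that test recovered 3% of genes changed by a fold of 2 and 27.3% at a fold of 4. Few calls therefore do not show that the tissues responded alike. In the real data it called 3 genes, all lower in brain relative to colon. They were OMP (-5.42, adjusted p = 0.031), MAP3K1 (-2.45, adjusted p = 0.031) and RNPC3 (-1.97, adjusted p = 0.037). OMP, a marker of olfactory neurons, was at 47.0 CPM in vehicle brain replicate 2 and at most 0.94 CPM in the other vehicle brain library and 0.92 CPM in the treated ones.

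In SH-SY5Y cells, each treatment was first compared with the untreated cells of its labelled batch. The calls covered most of the genes tested: 11905 with supernatant, 11402 with butyrate and 11980 with oleoylethanolamide. The largest folds were of genes at or near 0 in one set of libraries. Supernatant-treated cells and the untreated cells of batch 2 shared 127 genes at no more than 10 counts that exceeded 5 CPM in every library of the other 3 groups, and 7 genes showed the reverse. The splicing factor gene PRPF8 lay between 614 and 692 CPM in butyrate, oleoylethanolamide and batch 1 untreated libraries and at no more than 2 counts in the others. EHMT2 and SMARCB1, both chromatin genes, and PRAME followed PRPF8, while CDC42, a small GTPase gene, and MATR3 did the opposite, with CDC42 between 282 and 320 CPM in the supernatant set and at most 2.04 CPM elsewhere. The 2 untreated groups differed from each other in 11089 genes.

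The treatments are therefore described against the untreated libraries of the same gene set, a choice made after seeing the data. Against these, 8204 genes were called with supernatant, 601 with butyrate and 10161 with oleoylethanolamide. Against the labelled batch 84.3%, 83.5% and 76.9% of these calls had the same direction; both forms use the same treated libraries, which alone favours this, and no value without an effect was computed. The direction held for 34 of 36 named genes with supernatant, 13 of 18 with butyrate and 41 of 42 with oleoylethanolamide. Untreated cells of the matching set carry another batch label, and those of the labelled batch belong to another gene set, so neither form isolates the treatment.

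Against untreated cells of the same gene set, stress-response genes were higher with bacterial supernatant. Genes of cell division and of the noradrenergic neuron type were lower. The labels name no control with bacterial culture medium or with solvent, so effects of these cannot be told apart from those of the treatments. Against the labelled batch none of the lists described here passed with an estimated correlation: adjusted p was 0.36 for the integrated stress response, 0.61 for NRF2 targets, 0.61 for p53 targets, 0.71 for NF-kB, 0.61 for glycolysis, and 0.91 for proliferation, the noradrenergic list and neuronal differentiation. Proliferation genes then went both ways (13 higher, 13 lower), and the noradrenergic median was 0.27. Within the same gene set the test called 4210 higher and 3994 lower genes. GDF15, a stress-induced hormone gene, averaged 135 CPM with supernatant and 8.58 CPM without (log2 fold change 3.97, adjusted p = 5.7e-16). In the integrated stress response, which answers amino acid shortage and protein stress, 19 of 21 genes were higher, and as many adjusted over the list alone, with CHAC1 (3.66), ATF3 (2.74), SESN2 (1.86) and DDIT4 (1.01); the list passed with an estimated correlation (adjusted p = 0.0094). Targets of the antioxidant factor NRF2 rose in 17 of 19 cases, led by HMOX1 (3.60), OSGIN1 (3.48) and NQO1 (2.33). As many rose adjusted over the list alone, and that list passed with an estimated correlation (adjusted p = 0.015). SQSTM1, a gene of the lysosome and autophagy list, rose by 1.06. Of 21 p53 targets 17 rose, and 17 adjusted over the list alone, with the cell cycle inhibitor gene CDKN1A at 1.82 and the death gene BBC3 at 1.37 (adjusted p = 0.013 with an estimated correlation). The inflammatory genes CCL2 (1.72) and NFKB2 (1.17) were among 11 higher of 12 NF-kB genes (11 adjusted over the list alone; adjusted p = 0.032 with an estimated correlation).

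Mitotic genes fell with supernatant, 19 of 30 in the proliferation list and 19 adjusted over the list alone (adjusted p = 0.043 with an estimated correlation), with CENPE at -1.58, PLK1 at -1.40, KIF20A at -1.31 and CENPF at -0.96. Glycolysis genes fell too, 21 of 28 (21 adjusted over the list alone; adjusted p = 0.030 with an estimated correlation), with LDHA at -1.19, SLC2A1 at -1.11 and HK2 at -1.09. TFAP2B (-1.78), the noradrenaline transporter gene SLC6A2 (-1.24) and GATA2 (-0.61) stood among 11 lower of 17 noradrenergic identity genes (11 adjusted over the list alone; adjusted p = 0.046 with an estimated correlation), and MAP2 (-0.83) and DCX (-0.75) among 15 lower of 20 neuronal differentiation genes (15 adjusted over the list alone; adjusted p = 0.046 with an estimated correlation). Autism risk genes were lower in 26 of 34 cases, with MYT1L at -1.47, AUTS2 at -1.12 and TCF4 at -0.97, though the list did not pass with an estimated correlation (adjusted p = 0.12). The mitochondrial transcripts MT-ND5 (-0.75) and MT-CYB (-0.35) and the lipid synthesis genes FASN (-0.87) and SCD (-0.72) fell, as did RTL1 (-2.40). PPP1R1B, a dopamine signalling gene (2.87), the retinoic acid binding gene CRABP2 (2.02) and COL1A1 (1.87) rose. COL1A1 (-0.48) and GATA2 (0.078) had the opposite sign against the labelled batch.

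Oleoylethanolamide raised mesenchymal, inflammatory, antigen presentation and lysosome genes in the cells. It lowered mitochondrial transcripts, cell division genes and neuronal genes. Against the labelled batch the mesenchymal, proliferation and neuronal lists passed as well. NF-kB, lysosome and mitochondrial genes did not (adjusted p = 0.070 with an estimated correlation for each). The mesenchymal list also passed there with butyrate (13 of 16 higher, adjusted p = 0.0074 with an estimated correlation), so that result is not particular to oleoylethanolamide. The proliferation and neuronal lists did not pass there with butyrate (adjusted p = 0.19 with an estimated correlation for each). By camera with its preset correlation both were lower with butyrate too. Of proliferation genes 24 of 30 fell (adjusted p = 0.00069), and of neuronal differentiation genes 14 of 21 (adjusted p = 0.0033). Passing with 1 treatment and not the other there does not set the 2 treatments apart. Antigen presentation cannot be judged there, since HLA-B, HLA-E, TAP1 and TAPBP are among the genes near 0 in those untreated cells. The test called 5162 higher and 4999 lower genes. CEMIP, whose product breaks down hyaluronan, averaged 285 CPM with treatment and 13.6 CPM without (log2 fold change 4.39, adjusted p = 1.6e-32). Of 16 mesenchymal genes 15 rose, and 15 adjusted over the list alone (adjusted p = 0.0017 with an estimated correlation), with COL3A1 at 2.06, CD44 at 1.94 and FN1 at 1.88. All 12 antigen presentation genes of MHC class I rose, likewise adjusted over the list alone (adjusted p = 0.0017 with an estimated correlation), with HLA-E at 2.01, HLA-C at 1.82 and B2M at 1.40. NF-kB genes rose in 13 of 14 cases (13 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation), with CCL2 at 2.13, ICAM1 at 2.06 and NFKBIA at 1.41. Lysosome and autophagy genes rose in 18 of 20 (18 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation), with CTSD at 1.74, SQSTM1 at 1.63 and CTSB at 1.52. The crosslinking enzyme gene TGM2 (4.04), the prostaglandin synthase gene PTGS1 (3.68), the cytokine gene TSLP (3.66), HSD11B1 (3.59) and CEBPD (3.23) were among the largest increases. The PPARA target genes ANGPTL4 (1.07) and PLIN2 (0.95) were among 9 higher and 3 lower of 22, in a list that was not called by camera (adjusted p = 0.28). The ferritin genes FTH1 (1.63) and FTL (1.33) and HMOX1 (2.00) rose, and GDF15 (2.34), CDKN1A (1.42) and the lactate exporter gene SLC16A3 (2.15) rose.

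In the other direction, 12 of 13 transcripts of the mitochondrial genome fell with oleoylethanolamide (12 adjusted over the list alone; adjusted p = 0.041 with an estimated correlation), with MT-ND5 at -1.24, MT-CO3 at -1.14 and MT-CYB at -1.01. Of 30 proliferation genes 29 fell, and 29 adjusted over the list alone, including MKI67 (-0.73) and TOP2A (-0.66) (adjusted p = 0.016 with an estimated correlation). Neuronal differentiation genes fell in 16 of 21 cases (16 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation), with ELAVL3 at -0.83, MAP2 at -0.79 and DCX at -0.68. The glutamate receptor gene GRIA2 (-1.85), MIAT (-1.70), DLK1 (-1.64), PDK1 (-1.55), TFAP2B (-1.14), SLC6A2 (-1.09), SNAP25 (-0.85) and the noradrenaline synthesis gene DBH (-0.81) fell. DCX had the opposite sign against the labelled batch (0.30).

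Butyrate gave a small response, led by TFPI2, SLC6A3 and retinoic acid binding genes among higher genes and CBLN2 and INSM2 among lower ones. Of these, CRABP2 (-1.51), CRABP1 (-0.10), INSM2 (0.17) and CBLN2 (0.10), and also CHGA (3.45), had the opposite sign against the labelled batch. It called 389 higher and 212 lower genes, of which 16 passed a fold of 2. The count was 351 without untreated replicate 3 of batch 1, 367 without butyrate replicate 2, 369 without butyrate replicate 1 and 397 without untreated replicate 2 of that batch. TFPI2, a protease inhibitor gene, rose from 66.8 to 121 CPM (log2 fold change 0.86, adjusted p = 5.7e-11). The dopamine transporter gene SLC6A3 (0.87), the retinoic acid binding genes CRABP2 (0.73) and CRABP1 (0.65), ITPR3 (0.69), the neurotrophin receptor gene NTRK3 (0.48), COL1A1 (0.42), NOTCH3 (0.32) and COL3A1 (0.23) rose. Of 16 mesenchymal genes 4 were called, 6 adjusted over the list alone (adjusted p = 0.077 with an estimated correlation). CBLN2 (-0.73), INSM2 (-0.48), the granule protein gene CHGA (-0.32), TFAP2B (-0.26) and SNAP25 (-0.19) fell, as did the carnitine carrier gene SLC25A20 (-0.27) and the cholesterol synthesis gene FDFT1 (-0.18). GDF15 (0.35) and CCL2 (0.18) rose slightly. SLC16A1, through which butyrate enters cells, was not called (0.075, adjusted p = 0.27).

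**Figure D4:**
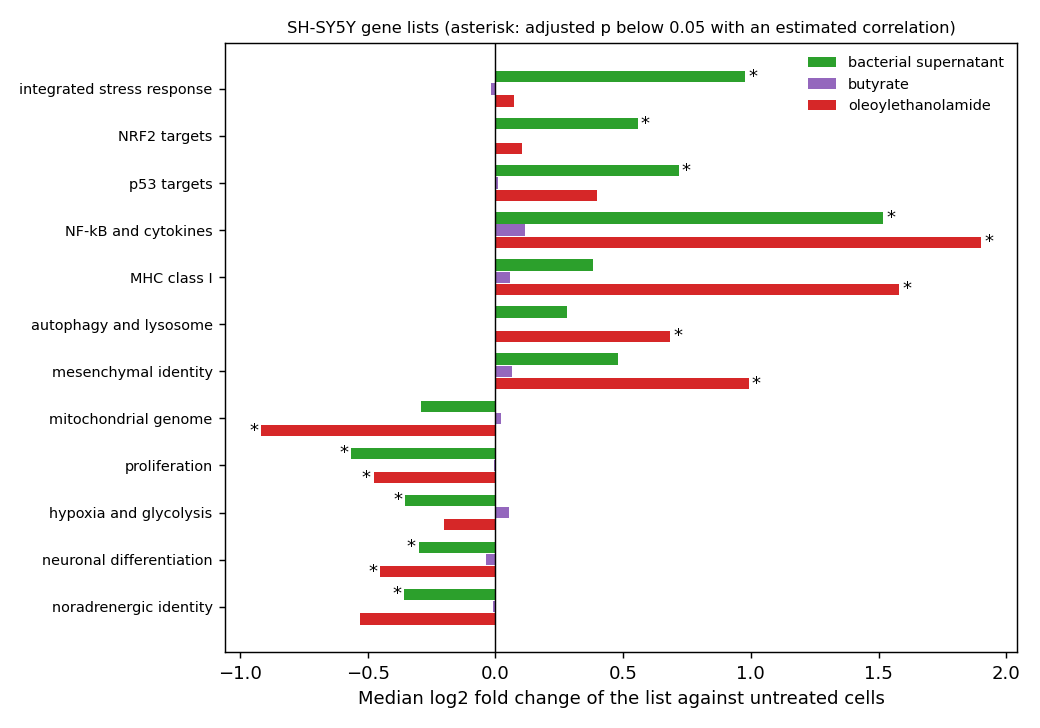
Median log2 fold change (x axis) of 12 gene lists (y axis) in SH-SY5Y cells treated with bacterial supernatant, butyrate or oleoylethanolamide, against untreated cells of the same gene set; an asterisk marks an adjusted p below 0.05 with an estimated correlation. The integrated stress response list has a median of 0.98 with supernatant and 0.073 with oleoylethanolamide.

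Oleoylethanolamide and butyrate share a labelled batch and a gene set, so their direct comparison needs no untreated cells. It called 9866 genes, 5081 higher and 4785 lower with oleoylethanolamide. CEMIP (4.16), TGM2 (3.59), HSD11B1 (3.43), COL3A1 (1.83), CD44 (1.86), FN1 (1.78), ICAM1 (2.04), CCL2 (1.96) and NFKBIA (1.34) were higher, and so were HLA-B (1.97), HLA-E (1.93), HLA-C (1.71) and B2M (1.36). CTSD (1.82), SQSTM1 (1.48), CTSB (1.43), FTH1 (1.59) and FTL (1.37) were higher as well. DLK1 (-2.00), MIAT (-1.82), MT-ND5 (-1.32), MT-CO3 (-1.17), NRCAM (-0.85), MKI67 (-0.85), ELAVL3 (-0.83), TOP2A (-0.75), CENPF (-0.73) and MAP2 (-0.71) were lower. The lists of MHC class I, mesenchymal, lysosome, NF-kB, proliferation, neuronal differentiation and mitochondrial genome genes each passed with an estimated correlation (adjusted p between 0.0029 and 0.027).

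Whether supernatant acted like oleoylethanolamide or butyrate was tested from the difference of effects. The integrated stress response was higher with supernatant than with oleoylethanolamide (18 of 22 genes, adjusted p = 0.0014 with an estimated correlation), with CHAC1 at 3.10, ATF3 at 2.67, STC2 at 2.44, PSAT1 at 1.35, MTHFD2 at 1.31 and PHGDH at 1.09. Mesenchymal genes were lower (10 of 16, adjusted p = 0.0017 with an estimated correlation), with COL3A1 at -2.13 and FN1 at -1.62, though COL1A1 went the other way (1.52). Against the labelled batch the integrated stress response did not differ by this test (10 higher, 8 lower, adjusted p = 0.62 with an estimated correlation) and CHAC1 stood at -0.76. Mesenchymal genes were lower there (14 of 16, adjusted p = 0.00022 with an estimated correlation), where each treatment is set against untreated cells of the other gene set. CEMIP (-3.33), TNC (-2.5), TGM2 (-2.29), CTSD (-1.27), CTSB (-1.26) and FTH1 (-1.11) were lower and NQO1 (1.75) and MT-CO3 (0.94) higher, though NQO1 (-1.90) and COL1A1 (-3.09) had the opposite sign against the labelled batch. The difference called 6953 genes against untreated cells of the same gene set and 12962 against those of the labelled batch. Relative to butyrate the counts were 6723 and 13064, with CHAC1 (3.88), GDF15 (3.60), HMOX1 (3.19), CXCL8 (2.53) and NQO1 (2.17) higher and RTL1 (-2.54) and CENPE (-1.64) lower with supernatant. HMOX1 (-2.72), CXCL8 (-5.44) and NQO1 (-1.48) had the opposite sign against the labelled batch.

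Correlations were computed across genes, which are not independent replicates. Over 14854 genes, fold changes with supernatant and oleoylethanolamide had a Pearson correlation of 0.49 against untreated cells of the same gene set, and 4730 of the 5808 genes called in both had the same direction (2307 higher and 2423 lower, against 1326.8 and 1281 for independent lists). Against the labelled batch, over 15706 genes, it was -0.79. For supernatant and butyrate the values were 0.28 and -0.89. For oleoylethanolamide and butyrate, which share their untreated cells, they were 0.22 and 0.93, where simulated unchanged groups gave 0.51 and 0.50. The covariance was 0.0428 beside a simulated 0.0202 with cells of the same gene set, and 3.34 beside 0.0222 with the labelled batch. The simulated groups hold no difference between the gene sets, which the labelled-batch values contain. Those values, -0.79 and -0.89 among them, therefore cannot be read as shared or opposed responses to the treatments.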

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

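The tests of different gene references, exchanged batch labels, vehicle replicate 2, striatal tissue and time of day were chosen after the results they concern had been seen.

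In SH-SY5Y cells the libraries fell into 2 sets that cross the labelled batches. Lower depth is argued against: the 127 genes near 0 in supernatant and batch 2 untreated libraries would have a median of 1496 counts at the lowest depth of that set. Different gene references for the 2 sets may account for those 127 genes, since no gene split supernatant from batch 2 untreated libraries in this way. An exchange of the batch labels of the untreated libraries could also account for the sets, as 6 of 6 untreated libraries lay nearer to the treated libraries of the other batch with the genes near 0 left out. Both stay open, and no biological explanation was tested.

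The treatment calls in brain cortex rested on few vehicle libraries. Striatal tissue as the whole cause is argued against, since 1311 genes were called with the striatum list as a covariate. That covariate does not cover tissue of other regions, which was not tested. OMP, a marker of olfactory neurons, was at 47.0 CPM in vehicle replicate 2 and at most 0.94 CPM in the other BTBR brain libraries. Whether vehicle replicate 2 sets the calls stays open: 6 genes were called without vehicle replicate 2 and 1131 without vehicle replicate 3, but each count has 1 vehicle library and takes its spread from the other groups. A length bias between the groups may contribute: transcript length and fold change had a Spearman correlation of -0.31 across genes. With the covariate the median size of the 1811 calls went from 0.67 to 0.48 and the median standard error from 0.16 to 0.24, so that calls ended both where folds shrank, as for RPS23 (-0.11), and where folds held and errors grew, as for FLT1 (-0.93). The length trend follows the groups (correlation -0.89), and an effect of the bacterium stays open as well.

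Clock genes differed between the strains in colon. C57 replicate 1 as the whole cause is argued against, with 10 clock genes called without it, and so is the balance of epithelium and muscle, with 10 called under that covariate. Collection at another time of day cannot be told apart from a strain difference: the 10 genes had a median brain fold change of 0.28 in the colon direction, with 6 of 10 in that direction and 1 called, DBP, while HLF was called in the other. A strain difference in the clock is open and untested.

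Of 165 gene and group pairs, 41 had 1 library far from the others, so single values carry little weight. The threshold used would give about 8.2 for normally distributed values. Untransformed CPM were used and genes were partly chosen for large folds, so 8.2 is not a chance level for these pairs. C57 colon replicate 1 stood highest in 10 genes: HAL at 1.17 CPM, ST3GAL4 at 3206 CPM, CLDN4 at 841 CPM, DUOX2 at 896 CPM, DUOXA2 at 359 CPM, ABCG2 at 620.1 CPM, SLC16A3 at 326 CPM, ANPEP at 20255 CPM, APOA1 at 50614 CPM and REG3G at 9629 CPM. Vehicle colon replicate 7 stood highest in 5: LPO at 1279 CPM, TDG at 10.3 CPM, SP110 at 1.54 CPM, CSF1R at 96.3 CPM and IDE at 98.1 CPM. Vehicle colon replicate 2 was highest for ENO1 (530.3 CPM), STMN2 (105 CPM) and SEMG1 (98.8 CPM) and lowest for CDH1 (346 CPM). Other vehicle libraries stood highest for PAX5 (75.2 CPM) and CD79B (92.2 CPM) in replicate 8, CLDN8 (59.0 CPM) in replicate 6 and APOA1 (1.43 CPM) in replicate 3. Other C57 libraries did so for HSPA1A (338 CPM) in replicate 3, CD68 (16.5 CPM) in replicate 4 and ST6GALNAC1 (0.091 CPM) in replicate 5.

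Among treated colon libraries, replicate 1 was far above the others for SNAP91 (67.6 CPM), RET (134 CPM) and CNR1 (169 CPM), and replicate 10 for TAGLN (326 CPM), PAX5 (557 CPM) and S1PR1 (54.6 CPM). Replicate 4 stood out for AQP8 (498 CPM) and FFAR2 (190 CPM), replicate 5 for SEMG1 (1.46 CPM) and OR51E2 (23.9 CPM), replicate 2 for IFIT1 (2877 CPM), replicate 3 for RTL1 (5.95 CPM) and replicate 9 for STRC (0.14 CPM). In treated brain, replicate 2 was highest for PECAM1 (17.2 CPM) and NAAA (25.3 CPM). The treatment effects in brain and colon differed by a test of the difference for OMP (-5.42), MAP3K1 (-2.45) and RNPC3 (-1.97).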

How the results depend on the processing

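Settings that involve untreated cells of the same gene set, covariates for striatum, gut layers or length, divided brain controls and omitted gut libraries were chosen after seeing the data; the rest were planned. Unless stated, the cause was not tested. Of 4816 alternative values for named genes, 328 lost the call, 13 gained a call and 17 reversed. The other 4458 kept their side of the threshold, but not all kept their direction. Uncalled genes whose sign changed are among them, as NAAA (-0.361 to 0.012) and BSG (0.349 to -0.11) in brain treatment with the length covariate. They also hold 698 values of colon treatment genes, which had no call to lose. Over the planned comparisons, with the labelled batch for cells, gene list calls numbered 122, 22 with an estimated correlation and 200 by fry; with untreated cells of the same gene set, 8, 0, 7, 2 and 12 lists passed with an estimated correlation for supernatant, butyrate, oleoylethanolamide and the differences from oleoylethanolamide and butyrate.

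The brain strain count of 754 was 310 at a fold of 2, 1566 by DESeq2, 1269 by limma voom and 157 with the striatum list as covariate. Leaving out 1 library gave 85 (vehicle replicate 2) to 514; it was 125, 272 and 466 without C57 replicates 2, 1 and 3. The brain treatment count of 1811 (41.4% higher) was 361 at a fold of 2, 2826 by DESeq2 (55.2% higher), 562 with 1 surrogate variable and 0 with the length covariate, where 2213 passed unadjusted; RPL27 then stood at -0.081 and RPS23 at -0.11. Leaving out 1 library gave 6 (vehicle replicate 2) to 2760 (treated replicate 2), with 844, 1133 and 1131 without treated replicates 1 and 6 and vehicle replicate 3. The colon strain count of 1271 (33.7% higher) was 5033 by limma voom (49.6% higher), under which REG3G stood at 0.14, and 683 without 3 libraries of other gut regions. It ranged from 586 (without C57 replicate 1) to 1627, and was 822 without C57 replicate 2. In colon treatment limma voom called 3 genes, and leaving out any 1 library gave 0 to 0. The tissue difference of 3 genes was 6 by DESeq2 and 506 by limma voom. Opposite signs among strain calls alone numbered 647 in brain (85.8%, simulated 77%) and 707 in colon (55.6%, simulated 63%). With divided vehicle controls in brain, 2 and 9 genes were reversed, against 200.

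Replicate numbers did not pair the libraries: 0 of 7 same-numbered brain pairs and 7 of 19 colon pairs correlated above 0.1. With the replicate block the count was 31 for brain strain, 0 for brain treatment by edgeR and 510 for colon strain.

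At a fold of 2 the cell counts were 4327 for supernatant, 3119 for butyrate, 4095 for oleoylethanolamide, 1711 for oleoylethanolamide minus butyrate, and 7477 and 7722 for the supernatant effect minus those of oleoylethanolamide and butyrate. With all 6 untreated libraries they were 5946, 0 (by edgeR) and 6754 for the treatments. Against untreated cells of the same gene set they were 601 for butyrate and 6953 and 6723 for the differences, against 11402, 12962 and 13064 with the labelled batch. Within the same gene set, a fold of 2 left 1570 for supernatant, 16 for butyrate, 1784 for oleoylethanolamide, and 1310 and 1168 for the differences; butyrate gave 231 with all 15 libraries. Leaving out 1 library gave 11312 to 11866 for supernatant, 10765 to 11125 for butyrate, 11511 to 11725 for oleoylethanolamide and 9082 to 9400 for their difference, and within the same gene set 7061 to 7875, 351 to 633 and 9546 to 9781. Butyrate there gave 351 and 397 without untreated replicates 3 and 2 and 369 and 367 without butyrate replicates 1 and 2. Correlations of supernatant with butyrate were -0.89, -0.71 by Spearman and 0.28 within the gene set; with oleoylethanolamide -0.79, -0.46 and 0.49; of oleoylethanolamide with butyrate 0.93, 0.77 and 0.22. Against the labelled batch these genes reversed: with supernatant GATA2 (0.078) and COL1A1 (-0.48); with butyrate CRABP2 (-1.51), CRABP1 (-0.10), CHGA (3.45), INSM2 (0.17) and CBLN2 (0.10); with oleoylethanolamide DCX (0.30); for supernatant minus oleoylethanolamide CHAC1 (-0.76), NQO1 (-1.90) and COL1A1 (-3.09); for supernatant minus butyrate NQO1 (-1.48), HMOX1 (-2.72) and CXCL8 (-5.44). Depth limits rare genes most in colon, where the shallowest library held 2561466 counts.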

Other observations

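The splits within the same gene set concern comparisons chosen after seeing the data; the other splits were planned.

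Bacterium-treated BTBR mice were also set against C57 mice. In brain 3113 genes differed and in colon 2173. These comparisons share their C57 libraries with the strain comparisons, so their overlap is not interpreted.

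Other splits of the same libraries bear on the counts. For colon strain, chance is unlikely to give the count. Of 100 splits drawn from 2002 possible, 1, the real one, reached 1271 genes, and the highest other gave 158. C57 replicate 1 was part of these splits, and none were run without it, where the count was 586. For colon treatment the splits decide nothing, since any of the 100 must reach the real count of 0 by edgeR (1547 genes passed unadjusted, DESeq2 called 0 and limma voom 3); the highest other gave 94. The 10 splits of 3 against 3 libraries are too few for such a statement. The real and highest other values were 11905 and 0 for supernatant, 11402 and 0 for butyrate, 11980 and 0 for oleoylethanolamide, 9866 and 0 for oleoylethanolamide minus butyrate, and within the same gene set 8204 and 1, 601 and 2, and 10161 and 0. In each of these 1 split, the real one, reached the count.

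For the differences of effects with the labelled batch, 1 of 100 splits reached 12962 genes relative to oleoylethanolamide. The highest other gave 10478 and exchanges the treated and untreated libraries of oleoylethanolamide. Relative to butyrate 1 reached 13064 (highest other 8928). Here the treated and untreated libraries of each treatment belong to different gene sets, so splits that mix them also mix the sets. These splits therefore cannot exclude chance for a difference between treatments. Within the same gene set 2 of 100 reached 6953 (highest other 10478) and 4 of 100 reached 6723 (highest other 7308). There the highest other split exchanges the treated and untreated libraries of the second treatment. It thus tests the sum of both effects and still holds the supernatant effect. Brain splits were not run, because the vehicle group held 2 libraries.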
